A study of Homo sapiens with 3 samples.

How the data were processed

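The series profiled DNA bound by RING1B in HES-3, an established line of human embryonic stem cells that was made to express RING1B with an HA tag. RING1B is a ubiquitin ligase of Polycomb Repressive Complex 1, which marks histone H2A and keeps developmental genes silent. Per the labels, chromatin was crosslinked with 1% formaldehyde, sonicated and enriched with anti-HA agarose (HA ChIP) or with agarose-bound wheat germ agglutinin (WGA), a lectin that binds O-GlcNAc, in a second round of enrichment (WGA re-ChIP). What else the lectin retained was not tested. The labels list 3 samples: an HA ChIP, a WGA re-ChIP and an input, with 1 library each. Region lists of the HA ChIP and the WGA re-ChIP were analysed; a list for the input was not analysed here, and its reads enter only as far as the control columns hold them.

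Per the submitters' processing notes, the genome build was hg19 and the tools were STAR 2.3.0e, HOMER, SICER and bedtools, named without role, order or settings. Peaks were called per sample, since each list belongs to 1 library. Each library has a list of broad islands, of the form SICER writes, and a list of narrow peaks, of the form HOMER's findPeaks writes. In the island lists the authors deposited whole-number counts of ChIP and control reads per island, without normalization. The p-value and the false discovery rate (FDR) of each island are the authors' own, per the file headers. The deposited fold of an island is a ratio of ChIP to control reads divided by 1 factor per list, 1.05 for HA and 0.923 for WGA, and the ratio of these factors, 1.14, is the HA depth relative to the WGA depth. In the peak lists the authors deposited tags per peak as a signal scaled to a library size (HA tags to the control, WGA control tags to the WGA library), per the file headers, and WGA tags as unscaled counts. The focus ratio of each peak is a fraction between 0 and 1 and the findPeaks score is HOMER's own, per the file headers; neither was used to rank regions. Scores and folds are the authors' own values, and they served only to describe, rank or filter regions within a list.

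The lists were not filtered alike. The HA island list held no island with an FDR of 0.01 or more, its highest being 0.00989. The WGA island list held FDR values up to 1, with 9310 islands at 0.01 or more. The name of the control library is not given in the sources used here. Islands with identical coordinates occurred 48 times in the lists, and in 48 of these the control count was equal, so both lists were set against the same control reads. Total reads per library are not given in the sources used here, so depth is known as the ratio above. If HOMER's default scaling was used, which the headers do not state, the steps of the deposited normalized tags imply about 17900000 HA tags and 15600000 WGA tags.

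Island starts were converted to 1-based coordinates. Overlap meant at least 1 bp in common, computed in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and the main counts were checked against bedtools 2.31.1. Shares carry 95% Wilson intervals and ratios of island counts carry 95% intervals from the counts (scipy 1.17.1). These intervals cover counting error only; neighbouring islands are not independent, and with 1 library per group no replicate check and no test between libraries was possible. Chance placement was described with 100 seeded shuffles of the islands over their own chromosome, leaving out stretches of 1 Mb or more that held no region of either library, and with 100 local shuffles that moved each island by up to 500 kb. The local shuffles did not leave out such stretches. Neither kind of shuffle allowed for sequence to which reads cannot be mapped, so part of any excess over shuffling may come from that. As a check of the code, islands were placed on or off HA islands in set shares, with the same overlap routine. Islands placed at random were also compared with their own shuffle over the chromosome. The computed shares differed by at most 0.113 percentage points over 68312 regions. This does not test whether the shuffles describe chance, and the local shuffle was not checked. Figures were drawn with matplotlib 3.10.9.

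Chosen before the data were examined were the SICER islands as the main set, the overlap rule, the shuffle over the chromosome, the alternatives with HOMER peaks, with the top 50% of islands by fold, with the 5000 islands of highest fold, with at least 50% of an island overlapped and with a reach of 5 kb, and the rule for named regions. That rule takes the 10 islands of each library with the highest fold, and the 10 with the highest fold among those without an island in the other library, among islands with an FDR under 0.01 and at least 20 ChIP reads, with ties in genomic order. The rule was written for genes at promoters and was applied to islands. An island with 0 control reads has a deposited fold that depends on a small constant, so its fold is given against 3 control reads and written as "at least". That bound would hold for a Poisson count, but control reads varied more than a Poisson count does. The true fold of such an island can therefore be lower. Chosen after the data were seen were the FDR limit of 0.01 for both lists, the local shuffle, the 2 Mb distance to stretches without regions, the 30-tag limit for tall peaks, the grouping of chromosomes by textbook gene density (16, 17, 19 and 22 against 4, 13, 18 and X) and 6 of the 7 rankings used to take 5000 islands of each library.

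The reference gene table used for names is of the assembly GRCh38.p14, which differs from the build of the lists, so no gene could be placed at an island. The 7 planned results on promoters, on 16 preset gene lists and on genomic location were therefore not run, and the gene content of every region below is not analysed here.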

Results

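The data consisted of region lists from 1 HA ChIP library, which sampled DNA bound by HA-tagged RING1B of any form, and 1 WGA re-ChIP library, described in the labels as DNA bound by the O-GlcNAcylated form, both from HES-3 human embryonic stem cells. All coordinates are of the build hg19. The lists held 48733 HA islands and 68336 WGA islands. HA islands covered 175.5 Mb and WGA islands 194.4 Mb of about 2830 Mb of sequence in which any region was found. The HA library was 1.14 times as deep as the WGA library, and neither has a replicate.

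HA-RING1B islands were broad and of moderate height. The median HA island was 3400 bp wide and held 50 ChIP reads and 20 control reads, with a median deposited fold of 2.38 (quartiles 1.84 and 3.41). The median WGA island was narrower, at 2600 bp, with 37 ChIP reads, 17 control reads and a fold of 2.44 (quartiles 1.76 and 3.79). HA islands held 15.8 ChIP reads per kb against 6.60 control reads per kb, and WGA islands 14.8 against 7.35. The lists differ in their limits: 9310 WGA islands had an FDR of 0.01 or more and no HA island did. At an FDR under 0.01 the WGA list held 59026 islands over 164.7 Mb with a median fold of 2.71. The island numbers are those of 2 lists with unequal limits and do not measure a difference in binding.

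The narrow HOMER peaks gave another order of the libraries. HOMER listed 32009 HA peaks of 195 bp and 7227 WGA peaks of 125 bp. The median HA peak held 11.4 tags after scaling to the control, and the median WGA peak 10 tags. The lowest listed peaks held 10.5 and 10 tags, so most peaks lay near the limit of the calling. Control tags were at their floor in 99.98% of HA peaks and 96.85% of WGA peaks. The peak numbers therefore do not measure a difference in binding. Of the HA peaks 43.3% lay in an HA island (95% interval 42.7 to 43.8%), against 9.53% after local shuffling. Of the WGA peaks 66.1% lay in a WGA island (65.0 to 67.2%), against 9.41%. Of the WGA islands 6.87% held a WGA peak, against 0.984% after local shuffling, and of the HA islands 26.5% held an HA peak, against 5.99%. Relative to shuffling the order was reversed, at 6.98 times for WGA and 4.43 times for HA.

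The islands of highest fold in each library had no control reads at all. The deposited fold of such an island rests on a small constant, which places these islands first. The ranking therefore does not show where binding was strongest. Folds written as "at least" are not strict lower bounds. They assume a Poisson count of control reads, and control reads varied more than that, so the true fold can be lower. In the HA ChIP the first was on chromosome 14 at 73207601 to 73210600, with 76 ChIP reads and 0 control reads, which is at least 24.1-fold. It was followed by chromosome 1 at 242827001 to 242831200 with 65 ChIP reads (at least 20.6-fold), and by chromosome 8 at 55751401 to 55755400 and chromosome 10 at 102832001 to 102833200 with 60 ChIP reads each (at least 19.1-fold). None of these 4 overlapped a WGA island. Of the first 10 HA islands, 1 overlapped a WGA island: chromosome 11 at 394601 to 397600 had 59 HA reads over 0 control reads, and its WGA island held 44 reads over 11 control reads, a fold of 4.33. The 10 islands held 56 to 76 ChIP reads and were at least 17.8-fold to at least 24.1-fold.

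The WGA re-ChIP led with other places, and there too the true fold can be lower than a value written as "at least". Its first island lay on chromosome 18 at 22118401 to 22122200, with 63 reads and 0 control reads (at least 22.8-fold) and no HA island. Its next, on chromosome 5 at 74950001 to 74952400, held 62 reads over 0 control reads (at least 22.4-fold) and overlapped an HA island with 66 reads over 5 control reads, a fold of 12.6. On chromosome 18 at 48190201 to 48193000 a WGA island with 59 reads over 0 control reads overlapped an HA island of fold 2.10, with 119 reads over 54. On chromosome 8 at 99291201 to 99294800 a WGA island with 50 reads over 0 control reads overlapped an HA island of fold 4.65. In all, 3 of the first 10 WGA islands overlapped an HA island. Among WGA islands with no HA island, the next after chromosome 18 were chromosome 13 at 110024801 to 110027000 and chromosome 15 at 92929601 to 92933600, with 55 reads each (at least 19.9-fold), and chromosome 4 at 10364201 to 10366400, with 52 reads (at least 18.8-fold). The absence of an island in a list means that none passed its caller, not that no reads were there.

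The WGA sample is titled a re-ChIP, which implies that it was made from chromatin already enriched for HA-RING1B. If so, a WGA island without an HA island does not show a place free of HA-RING1B. The overlap describes how far the called lists coincide. Of the WGA islands, 16794 of 68336, or 24.6% (95% interval 24.3 to 24.9%), overlapped an HA island. Shuffled over their chromosomes, 11.6% did so, and shuffled within 500 kb, 16.4%. The observed share was thus 2.11 times and 1.498 times the shuffled one. Of the HA islands, 16192 of 48733, or 33.2% (32.8 to 33.7%), overlapped a WGA island, against 15.9% and 22.3% after the same shuffles, which is 2.09 and 1.49 times. The sequence shared by both sets came to 33.4 Mb, 19.02% of the HA length and 17.2% of the WGA length. Most islands of either library therefore had no island of the other on them. With the narrow peaks only 83 regions overlapped, 1.15% of WGA peaks and 0.259% of HA peaks, 3.01 and 3.13 times the shuffled shares. Both lists used the same control reads, so part of any excess over shuffling may come from that control, and unchanged libraries could not be simulated from lists without genome-wide reads.

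**Figure D1:**
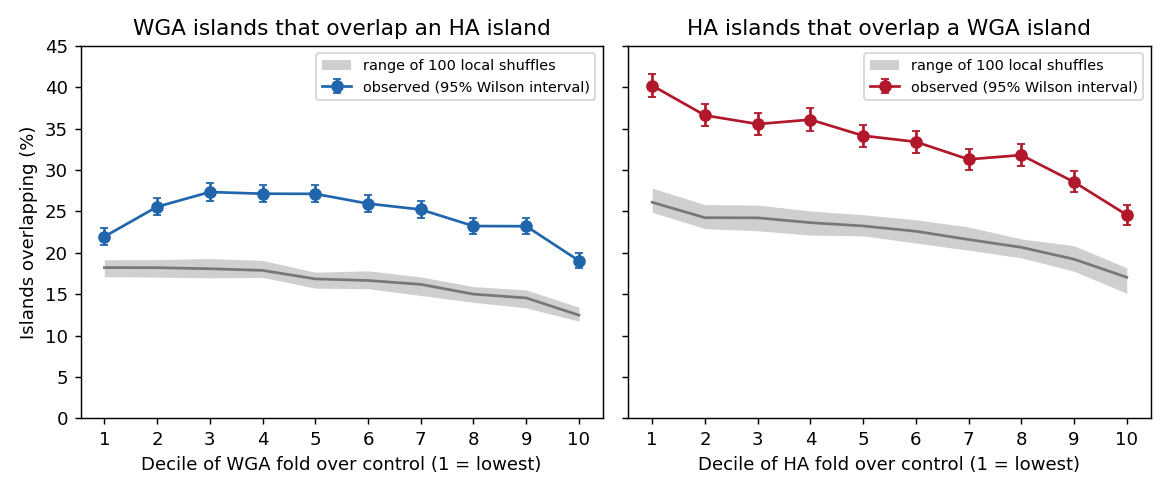
Percent of islands that overlap an island of the other library (vertical axis) by decile of the island's own deposited fold over control, from 1 (lowest) to 10 (horizontal axis), for WGA islands on the left and HA islands on the right. Points are observed shares with 95% Wilson intervals, and the grey line and band are the mean and range of 100 local shuffles; the HA share falls from 40.2% in decile 1 to 24.6% in decile 10, and the shuffled share falls with it.

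The islands of highest fold were not those that overlapped the other library most often. Among HA islands the overlap was 40.2% in the lowest decile by fold and 24.6% in the highest, while the local shuffle fell from 26.1% to 17.04%. The HA islands of the highest decile were narrower (median 2200 bp against 4200 bp). The ratio of observed to shuffled share was 1.54 in the lowest and 1.44 in the highest decile. Among WGA islands the overlap was 21.9% in the lowest decile, 27.3% in decile 3 and 19.04% in the highest, and the ratio was 1.21 in the lowest decile, which has a median fold of 1.19, and 1.53 in the highest. Fold, which is computed from both counts, ranked islands more by their control than by their ChIP reads: across islands with control reads its Spearman correlation with control reads per kb was -0.81 for HA and -0.84 for WGA, and with ChIP reads per kb 0.37 and 0.41. Islands are not independent replicates, so these describe the lists only.

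Some overlapping islands had a high deposited fold in both libraries. Among 15517 overlapping pairs of an HA island and a WGA island with an FDR under 0.01, both folds were 2 or more in 7991 pairs (51.5%) and 5 or more in 511. The folds of a pair rest on the same control library, so few control reads raise both, and no value for unrelated libraries could be set beside these counts. Across the pairs, ChIP reads per kb of the HA and the WGA island had a Spearman correlation of 0.042, so read densities were not ranked alike. Calling may limit the spread of read density within the lists, so this low value does not decide on shared binding. The following pairs were chosen after their values were seen, as those with at least 3 control reads and the highest lower fold. On chromosome 5 at 102181001 to 102182400 the HA island held 45 reads over 3 control reads (fold 14.3), and the WGA island over it, from 102179801 to 102182600, held 41 over 3 (fold 14.8). On chromosome 17 the HA island at 58246001 to 58248600 had a fold of 14.3 and the WGA island at 58247001 to 58249600 a fold of 12.7. On chromosome 16 the HA island at 65065201 to 65069400 had a fold of 12.4 and the WGA island at 65063401 to 65067400 a fold of 22.03. On chromosome 8 the HA island at 144411801 to 144414800 had a fold of 12.1 and the WGA island at 144411401 to 144415200 a fold of 16.2. On chromosome 9 at 132275801 to 132280000 the HA island held 63 reads over 5 control reads (fold 12.01), and the WGA island 59 over 5 (fold 12.8).

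Both libraries had most islands per Mb on chromosome 22, with 37.5 HA islands and 46.8 WGA islands. Chromosome 19 came next for HA (31.5 HA and 35.6 WGA islands per Mb) and chromosome 20 for WGA (29.95 and 38.5). Chromosome 4 had 9.26 and 15.4, chromosome 13 had 10.6 and 17.5, and the X chromosome 11.6 and 18.04, against 17.2 and 24.1 over 23 chromosomes together. In 2873 bins of 1 Mb the island numbers of the libraries had a Spearman correlation of 0.92 across bins, and in 28345 bins of 100 kb one of 0.60. Bins are not independent replicates. Both lists used the same control reads, and no value for unrelated libraries could be set beside these correlations. They therefore do not measure shared binding.

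HA islands were relatively more frequent on the chromosomes grouped as gene-dense than on those grouped as gene-poor. With WGA islands held at an FDR under 0.01, there were 1.01 HA islands for each WGA island on chromosome 19 (95% exact interval 0.948 to 1.08), against 0.690 on chromosome 4 (0.649 to 0.734) and 0.688 on chromosome 13 (0.635 to 0.746). At that limit the ratio was higher on the gene-dense chromosome in 16 of 16 pairs of a gene-dense and a gene-poor chromosome. Chromosome 21, in neither group, had 0.907 (0.815 to 1.01), against 0.900 (0.847 to 0.955) on the gene-dense chromosome 16. The gene-poor chromosome 18 had 0.810 (0.749 to 0.876), near the 0.826 of 23 chromosomes together. With the lists as deposited, chromosomes 16, 17, 19 and 22 together held 0.819 HA islands for each WGA island, and chromosomes 4, 13, 18 and X held 0.635. The first ratio was 1.29 times the second (1.23 to 1.35). HOMER peaks gave 4.74 and 4.21 HA peaks for each WGA peak, a ratio of 1.13 (1.02 to 1.25), which was 1.11 (0.997 to 1.23) without chromosome 22. The chromosome groups were set after the densities had been seen, and the intervals leave out any variation between libraries.

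**Figure D2:**
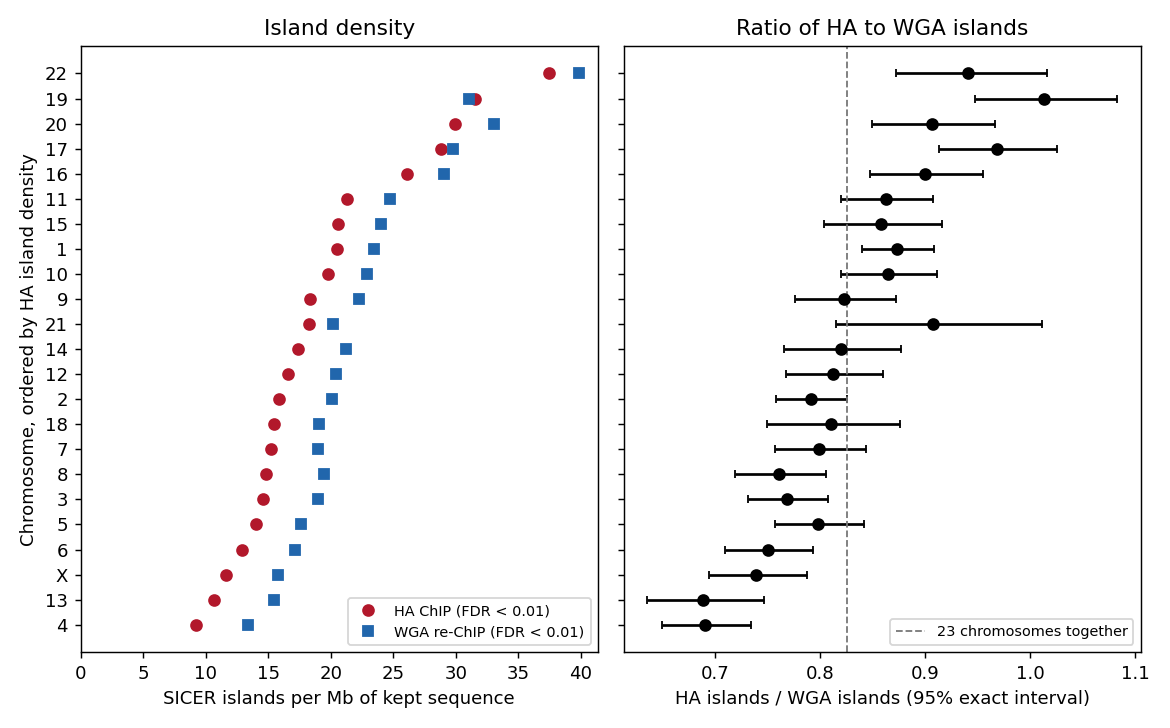
SICER islands per Mb of sequence with regions (left, horizontal axis) and HA islands divided by WGA islands with 95% exact intervals (right, horizontal axis) for each chromosome (vertical axis, ordered by HA density), with both lists at an FDR under 0.01. Circles are the HA ChIP and squares the WGA re-ChIP on the left; the ratio runs from 0.688 on chromosome 13 to 1.01 on chromosome 19, and the dashed line marks 0.826 for 23 chromosomes together.

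The WGA HOMER list held 278 peaks with at least 30 tags, and most lay near long stretches in which neither library had a region. Within 2 Mb of a stretch of 1 Mb or more without any region lay 83.8% of them (95% Wilson interval 79.0 to 87.7%), against 3.47% of the other WGA peaks (3.06 to 3.93%) and 2.13% of the HA peaks. Only stretches between regions were counted. Peaks beside the sequence before the first or after the last region of a chromosome were not counted as near for that reason. None of the 278 overlapped an HA peak (0%, interval 0 to 1.36%). The 30-tag limit was set after the tags had been seen.

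**Figure D3:**
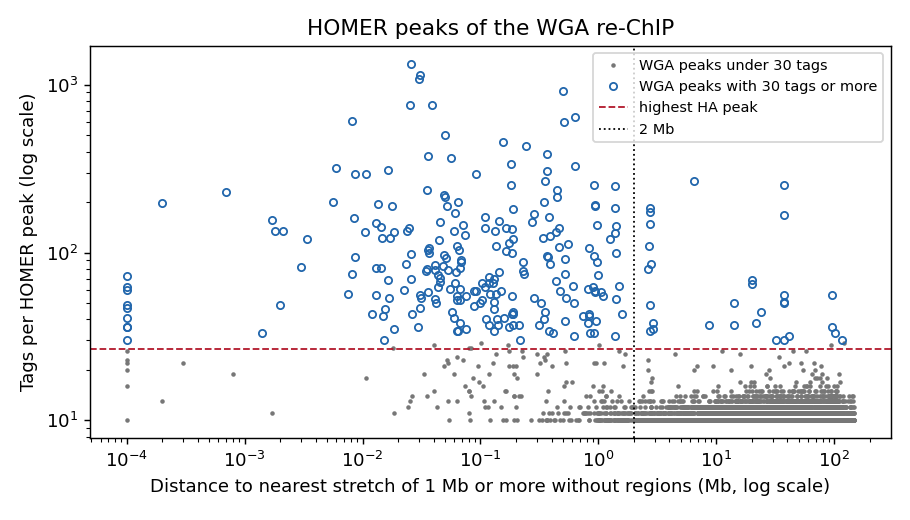
Tags per WGA HOMER peak (vertical axis, log scale) against the distance of the peak to the nearest stretch of 1 Mb or more without any region (horizontal axis, Mb, log scale). Only stretches between regions count, not the sequence before the first or after the last region of a chromosome. Peaks at such an edge are drawn at the left end, and peaks on chromosomes without a stretch between regions are left out. Open circles are the peaks with 30 tags or more, dots the others, the dashed line the highest HA peak at 26.7 tags and the dotted line 2 Mb; most open circles lie left of the dotted line.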

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

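The 30-tag limit, the 2 Mb distance, the test of multi-copy sequence and the overlap with HA islands were chosen only after the tag heights and positions had been seen, with limits of 15, 100 and 250 tags and a distance of 1 Mb also looked at. The WGA HOMER list held 278 peaks with at least 30 tags, whereas the highest of the 32009 HA peaks had 26.7 tags; they stand out because the comparisons of islands do not use tag heights. The highest lay on chromosome 10 at 42380192 to 42380316 with 1334 tags over 52.6 control tags, followed by chromosome 10 at 42385491 to 42385615 with 1143 tags over 12.9.

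Of the tall WGA peaks 83.8% (95% Wilson interval 79.0 to 87.7%) lay within 2 Mb of a stretch of 1 Mb or more without any region. A centromere or assembly gap can form such a stretch, and only stretches between regions were counted. Among the other WGA peaks 3.47% did, so that multi-copy sequence collapsed in the assembly is a candidate explanation. For tall peaks the share was 60.1 to 88.6% at the other limits tried. Repeated tags at the same positions may also contribute: at least 28 tall peaks held over 2 tags per base, more than the positions on both strands allow without repeats. In 71 of the 87 WGA islands that hold a tall peak, the HOMER tags outnumber the island's own SICER reads. The median SICER fold of these 87 islands was 1.28, against 2.44 for all WGA islands. Control tags were above their floor at 196 of the tall peaks (70.5%), against 0.46% of the other WGA peaks. The control was thus raised at most of these places too. Of the tall peaks 42.5% lay in a WGA island, against 67.0% of the other WGA peaks. HA-RING1B bound at the same sites stays open: 0 of the 278 tall peaks (interval 0 to 1.36%) overlapped an HA HOMER peak, an interval that holds the 1.19% of the other WGA peaks, while 24.1% (19.4 to 29.5%) lay in an HA SICER island (4.12% after local shuffling, which can move a peak into a stretch without regions), against 14.1% of the other WGA peaks (9.21% after shuffling), and the 48 HA islands concerned had a median fold of 1.51, against 2.38 for all HA islands.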

How the results depend on the processing

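Fixed before the data were examined were the alternatives with HOMER peaks, the top 50% and the 5000 highest islands by fold, at least 50% of an island overlapped and a reach of 5 kb; all others, and every ratio of chromosome groups, were chosen after the data were seen. Of 80 alternative values 9 moved by less than their counting interval, or by less than 1.5 times for counts. Some of these outcomes were fixed by the setting. The number of HA islands at an FDR under 0.01 could not move, and the numbers in the top 50% by fold had to. Observed overlap stayed above shuffled overlap in 30 of 30 values and the ratio of chromosome groups above 1 in 12 of 12. Directions thus held while sizes moved, and the cause was not tested. These values come from overlapping subsets of the same lists, so their number adds no independent support. Alternatives on promoters, gene lists and genomic location were not run, because no annotation of the lists' build was used here. No paired analysis was possible because each group has 1 library. What depth limits was not tested, and the HA library was 1.14 times as deep as the WGA library.

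Main shares were 24.6% (WGA) and 33.2% (HA). In the order WGA share, HA share, WGA over shuffle and HA over shuffle, the values were as follows. HOMER peaks gave 1.15%, 0.259%, 3.01 and 3.13. The top 50% by fold gave 13.6%, 18.9%, 2.75 and 2.74. The 5000 highest by fold gave 4.82%, 4.74%, 6.61 and 6.49. At least 50% overlapped gave 16.8%, 18.01%, 2.53 and 2.67, and a reach of 5 kb gave 43.4%, 56.4%, 1.74 and 1.68. An FDR under 0.01 in both gave 25.1%, 29.7%, 2.18 and 2.17. Islands holding a HOMER peak gave 6.82%, 2.44%, 2.38 and 2.34. Leaving out islands near gaps gave 2.17 and 2.14 over the shuffle, and the local shuffle of all islands 1.498 and 1.49.

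Taking 5000 islands of each library, 7 rankings were looked at. The lowest p gave 7.64%, 7.52%, 7.06 and 7.01, and away from gaps 7.62%, 7.48%, 7.06 and 6.99. The lowest p among islands with 5 control reads or more, also away from gaps, gave 8.26%, 8.20%, 5.47 and 5.39. The other rankings used ChIP reads alone, within the lists and away from gaps. By ChIP reads per kb, among islands of 1 kb or more, the values were 2.3%, 2.22%, 3.82 and 3.72. By ChIP reads they were 14.8%, 14.5%, 5.46 and 5.32. By excess over a fixed level of 6.2 reads per kb they were 7.76%, 7.56%, 6.03 and 5.99.

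HOMER peaks numbered 32009 (HA) and 7227 (WGA), the top 50% by fold 24366 and 34168, and islands holding a HOMER peak 12938 and 4694. The ratio of chromosome groups, 1.29 in the main set, was 1.13 with HOMER peaks and 1.54 with islands holding one. Among 5000 islands it was 1.47 by fold, 1.48 by p and 1.54 by p away from gaps. Also away from gaps, it was 1.21 by p with 5 control reads or more, 1.22 by reads per kb, 1.39 by reads and 1.43 by excess.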

Other observations

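The tests of unequal FDR limits, of the control through failing and passing islands, of the control through rankings, of SICER calling alone and with chromosomes left out were chosen only after the results they measure had been seen. Islands with few control reads were more common than counting error gives. Away from stretches without regions, the 4407 WGA islands of 2000 bp held 13.8 control reads on average with a variance 3.84 times the mean, and 100 of them (2.27%) held 0 control reads, where a Poisson count of that mean gives 0.000105%. The 3872 WGA islands of 3000 bp had a variance 4.18 times the mean. The mitochondrial chromosome had 1 WGA island, with 617 reads over 9642 control reads, and no HA island in a list that holds only islands above the control. The widest HA island, on chromosome 10 at 42355001 to 42400800, held 8480 reads over 7292 control reads (fold 1.11) and spans the 2 tallest WGA HOMER peaks.

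The modest overlap of HA and WGA islands does not follow from unequal FDR limits, since the WGA share was 25.1% with both lists at an FDR under 0.01. Dilution by weak islands stays open: the 5000 islands of each library with the lowest p-values overlapped at 4.76 times the local shuffle, which met the limit of 3 set before that value was seen, but these p-values use the control that both lists share, as does fold, by which the 5000 highest islands of each overlapped at 5.17 and 5.11 times, while by decile of fold against all islands of the other library the ratio went from 1.21 to 1.53 for WGA and from 1.54 to 1.44 for HA. Rankings by ChIP reads alone, within the lists and away from gaps, gave lower values. The excess was 2.35 times by ChIP reads per kb, 2.32 by ChIP reads and 2.69 by excess over a fixed level. The shared control may thus account for part of the higher value. A ranking with little information in it may do so too. ChIP reads in WGA islands of a given width had a variance of 0.722 times the mean at 2000 bp and 1.22 at 3000 bp. These are near counting error, though the value at 1200 bp was 3.96. The 2.35 exceeds the 1.498 of all islands by more than the range of the shuffles. It cannot decide on the control, because every HA island that was ranked had already passed an FDR limit against it. The sets compared also differ in size and filters. WGA islands that fail the FDR limit overlapped HA islands at 1.24 times the local shuffle, above the range of the shuffles. This does not decide on the control, since a local shuffle can move an island into a stretch without regions and so lower the shuffled share. For the islands that pass, at 1.54 times, the part of the control stays open as well.

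The higher ratio of HA to WGA islands on gene-dense chromosomes is not explained by unequal list sizes alone, since 5000 islands of each library with the lowest p-values gave a ratio of 1.48 (1.27 to 1.72), and 1.44 (1.23 to 1.69) or more with any 1 chromosome left out. Of the 7 rankings of 5000 islands, 5 kept an interval above 1 with any 1 chromosome left out, with ratios of 1.39 to 1.54 before, and 2 did not: the ratio by ChIP reads per kb, 1.22 (1.05 to 1.43), was 1.17 (0.993 to 1.38) without chromosome 19, and that by p among islands with 5 control reads or more, 1.21 (1.04 to 1.41), was 1.17 (0.996 to 1.38) without chromosome 13. SICER calling alone stays open, since the HOMER ratio of 1.13 (1.02 to 1.25) became 1.11 (0.997 to 1.23) without chromosome 22. HOMER peaks on the gene-poor chromosome 13 had a higher ratio of HA to WGA, 4.74, than those on the gene-dense chromosomes 16, 17 and 19 (4.63 to 4.71). The gene-dense chromosome had the higher HOMER ratio in 13 of 16 pairs of a gene-dense and a gene-poor chromosome. A difference in GC content between the libraries and a preference of the O-GlcNAcylated form for gene-poor sequence were not tested and could each give such a ratio. No biological explanation was tested.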
